A study of Mus musculus with 12 samples.

How the data were processed

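The data are a single deposited table of raw read counts per gene, whole numbers for 55401 Ensembl genes in 12 libraries, which the authors made from RNA sequencing of total RNA. Of these genes 55141 had a symbol and 260 did not. Every column was matched to its sample by name. Per the labels' protocols, total RNA was extracted with Trizol, only RNA with an integrity number above 7.0 was used, and inhibitors were applied for 4 h. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program, the gene annotation, the treatment of multiply mapping reads and whether counting used strand are not given in the sources used here, so counts of near-identical or overlapping genes are uncertain, antisense pairs included. Gene positions and types come from the GENCODE annotation of mm10, matched on the Ensembl gene identifier. Libraries were grouped by their titles into None, Kira8, Stattic and Kira8+Stattic, 3 libraries each, and the replicate numbers come from the same titles.

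Total counts ranged from 9.3 to 85.9 M (megacounts) per library, and from 51.7 to 85.9 M in the 10 libraries other than Kira8 replicate 2 and Stattic replicate 2. Replicates of a group were compared by a chi-square test of their counts over genes, and the lowest value per gene of any pair was 32.8 (Kira8 replicates 1 and 3), so no library was counted as a copy of another.

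From the counts as deposited, genes were kept by edgeR's filterByExpr with its defaults, scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) in a single fit with a coefficient per group. There were 7 comparisons: each inhibitor and the combination against None, the combination against each inhibitor, Stattic against Kira8, and the interaction, which is the Kira8 change with Stattic minus that without. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, 20993 in the 12 libraries and 21239 in the 10. The standard error of a log2 change is its size divided by the square root of the F statistic. Lists of genes, 45 in all, were tested in the first 6 of these comparisons with camera at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over lists with at least 3 tested genes. Each was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in a single direction. The lists, the comparisons, the tests and the alternatives were fixed before the data were examined.

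The fit of 10 libraries leaves out Kira8 replicate 2 and Stattic replicate 2. It was added after the data were examined, because of the library measures given for them. The fit of all 12 libraries remains the planned result, and both are reported. In the 10-library fit Kira8 and Stattic have 2 libraries each.

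Genes were named by a rule written before the data were examined. It takes 15 genes followed in every comparison, 14 of them given here (Ern1, Xbp1, Stat3, Il17a, Il17f, Il23r, Il10, Socs3, Bcl2, Bcl2l1, Mcl1, Bcl2l11, Hspa5 and Ddit3). It adds, for each comparison against None, the 10 genes higher and the 10 lower with the largest change among those called, with a mean of at least 5 CPM in the libraries compared and no overlap between the groups (5 and 5 in other comparisons, without the overlap condition for the interaction). Symbols made of Gm and digits or ending in Rik were left out. For each list up to 4 members with the smallest adjusted p complete the rule. In the 10 libraries it was applied in the same form after the data were examined. The text names part of the genes so chosen, and some further list members were named after their values were seen. Some genes the rule selected are not reported here.

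Alternatives were DESeq2, limma voom, RLE size factors, library size alone, no filter, a filter of more than 1 CPM in 3 libraries, a test against a 1.5-fold change, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Added after the data were examined were the 10-library fit with its own alternatives, the same fit with the replicate block, and limma voom with library quality weights on all 12 libraries. The shared effect of Kira8 and Stattic was set against 20 simulations of unchanged groups compared with the same None libraries. After the data were examined, 20 simulations each were added for the 10 libraries with unchanged groups, with equal Kira8 changes with and without Stattic, and with Kira8+Stattic kept at the Kira8 level (not used, since it fixes that comparison at no change), drawn from the group means and gene dispersions with independent libraries. Label splits were run on all 10 divisions of 3 against 3 libraries, and on 100 for the interaction, the real one and otherwise random ones.

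The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold between Stattic and None. In 12 simulated libraries (20993 genes) edgeR recovered 0% of the 2-fold and 0% of the 4-fold changes. In the 10 (21239 genes) it recovered 60% and 98%, with 11 calls among unchanged genes. In a separate simulation of the 10 libraries, a list of genes shifted 2-fold was the only list camera called. Genes were drawn independently there, so this does not test the preset correlation.

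The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.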

Results

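Messenger RNA was measured by sequencing in 12 libraries of mouse Th17 cells, the helper T cells that make IL-17. Naive T cells from wild-type lymph nodes had been driven toward the Th17 state and then given no inhibitor (None), Kira8, Stattic, or Kira8 and Stattic together for 4 h. There were 3 libraries per group. Kira8 inhibits IRE1alpha, the endoplasmic reticulum stress sensor encoded by Ern1 whose RNase activity starts the splicing of Xbp1 mRNA. Stattic inhibits STAT3, the transcription factor that acts downstream of IL-6, IL-21 and IL-23. The series names survival pathways of Th17 cells as its subject, so genes of cell death and survival were among those followed in every comparison. The labels do not say whether replicates came from separate cultures or animals, nor whether None received a solvent. All p-values therefore measure the spread between these samples, which may be technical.

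Total counts, in M (megacounts), were 62.9, 63.0 and 63.3 M in None and 51.7, 64.2 and 85.9 M in Kira8+Stattic. The Kira8 libraries held 59.1, 19.8 and 57.6 M, and the Stattic libraries 55.0, 9.3 and 53.7 M. Replicate 2 of Kira8 and replicate 2 of Stattic stood apart from the other 10 libraries. Mitochondrial transcripts took 61.55% of the counts in Kira8 replicate 2 and 10.66% in Stattic replicate 2, against 3.38% to 5.22% in the other 10. Olfactory receptor genes, which are silent in T cells, had counts for 39.8% and 32.7% of 1107 genes, against 4.1% to 10.2%. Gm10800, a gene model made of satellite-like repeat sequence, took 2.91% and 19.1% of the counts, against at most 0.01%. Spearman correlation across 14372 genes with the other 10 libraries was 0.41 to 0.45 for Kira8 replicate 2 and 0.36 to 0.39 for Stattic replicate 2, whereas the 10 correlated at 0.89 to 0.99 with each other. Genes are not independent replicates in these correlations. No pair of libraries within a group matched within sampling noise. A count of 3 corresponded to 0.0349 to 0.0581 CPM in the 10 libraries and to 0.151 and 0.323 CPM in the outlying ones. Such floors cover counting error only.

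**Figure D1:**
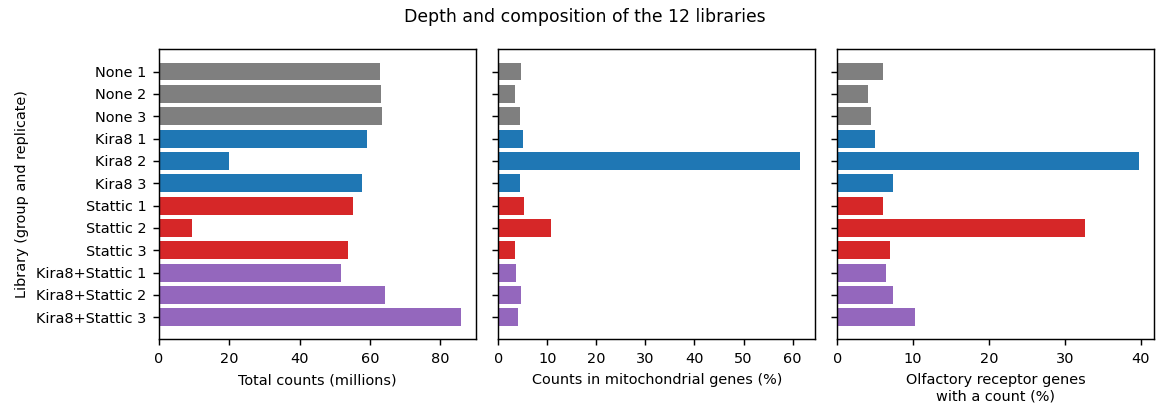
Bars for each of the 12 libraries show total counts in M and the percent of counts from mitochondrial genes. The last panel shows the percent of 1107 olfactory receptor genes with a count. Kira8 replicate 2 (19.8 M, 61.55% mitochondrial) and Stattic replicate 2 (9.3 M, 32.7% of olfactory receptor genes) lie apart from the other 10.

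The planned fit used all 12 libraries. Its common dispersion was 1.015, against 0.143 without the outlying pair. A fit of the other 10 libraries was added after the data were examined, and its values describe the genes below unless the 12 libraries are named. Each log2 change is given ± its standard error, with n = 3 for None and Kira8+Stattic and n = 2 for Kira8 and Stattic. Levels are TMM-scaled CPM ± SD over the same libraries. Calls are at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Coordinates are those of mm10. For lists of genes, the adjusted p of camera with a preset correlation is followed by the value with an estimated correlation, under which no list was called in any comparison.

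Kira8 was compared with None to ask what blocking IRE1alpha changes in Th17 cells. Among the genes that fell, Ifng, the type 1 effector cytokine, was 17.7-fold lower (-4.15 ± 0.55), the chemokine Ccl3 12.5-fold (-3.65 ± 0.30), the cytotoxic protease Gzmb 12.1-fold (-3.60 ± 0.30) and perforin, Prf1, 10.3-fold (-3.37 ± 0.37). Gzmb and Prf1 are also markers of CD8 T and NK cells, of which 10 of 14 fell. Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974, plus strand) fell from 26.0 ± 3.53 to 3.18 ± 1.07 CPM, 8.17-fold (adjusted p = 7.86e-05). Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand) was 718 ± 600 CPM in None and 152 ± 4.17 with Kira8, a change of -2.24 ± 0.53 (adjusted p = 0.0115). Il17f (chromosome 1, 20777146 to 20790617, minus strand) was 3.90-fold lower (-1.96 ± 0.46, adjusted p = 0.0107). Among the genes that rose most were the ESCRT-I gene Vps37b, 10.9-fold (3.45 ± 0.21), Casz1, 8.31-fold (3.06 ± 0.33), the phosphatidate phosphatase Lpin1, 7.83-fold (2.97 ± 0.20), and the chemokine receptor Cxcr4, 7.76-fold (2.96 ± 0.22). None replicate 2 carried much of the size of some falls: without it the changes were -3.51 for Ifng, -1.32 for Il17a and -1.24 for Il17f. The Il17a call ended without Kira8 replicate 1 (adjusted p = 0.0883) or replicate 3 (0.089), as did that of Il17f (0.0717 and 0.0975).

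The transcripts of the target and its substrate moved by smaller folds. Ern1 (ENSMUSG00000020715, chromosome 11, 106394650 to 106487852, minus strand) was 19.5 ± 7.17 CPM in None and 34.6 ± 1.38 with Kira8 (0.83 ± 0.27, adjusted p = 0.0495). Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893, plus strand) fell 1.64-fold (-0.72 ± 0.18, adjusted p = 0.0146), and Stat3 (chromosome 11, 100885098 to 100939540, minus strand) rose 1.40-fold (0.49 ± 0.15, adjusted p = 0.0409). Gene counts do not show how much Xbp1 mRNA was spliced. The Ern1 call ended without any single library other than None replicate 2 (adjusted p 0.0513 to 0.222), and the Stat3 call without any other than None replicate 3 and Kira8+Stattic replicate 3 (0.052 to 0.239). The Xbp1 call ended without Kira8 replicate 3 (0.219).

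Genes of secretory protein folding fell with Kira8. Of 16 ATF6 targets and ER chaperones 12 fell, none rose and 4 were not called, 13 lower when adjusted over the list alone (camera adjusted p = 1.14e-08; adjusted p = 0.228 with an estimated correlation). Examples are Sdf2l1 (-1.91 ± 0.17) and Pdia4 (-1.76 ± 0.19), and Hspa5, the chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), went from 1140 ± 454 to 478 ± 5.70 CPM (-1.25 ± 0.29, adjusted p = 0.00943). Of 28 targets of spliced XBP1, 9 fell, 3 rose and 16 were not called, 11 lower and 3 higher when adjusted over the list alone (camera adjusted p = 0.0252; adjusted p = 0.615 with an estimated correlation), with the oligosaccharyltransferase subunit Rpn1 at -1.23 ± 0.18. Of 8 measured substrates of IRE1-dependent mRNA decay 0 were called in edgeR, 0 also when adjusted over the list alone (camera adjusted p = 0.593; adjusted p = 0.864 with an estimated correlation). In contrast, Ddit3, the stress factor CHOP (ENSMUSG00000025408, chromosome 10, 127290774 to 127296288), rose 3.72-fold (1.90 ± 0.18, adjusted p = 7.61e-05), and 13 of 36 ATF4 and CHOP targets rose, 3 fell and 20 were not called, 15 and 4 when adjusted over the list alone (camera adjusted p = 0.002; adjusted p = 0.542 with an estimated correlation). Chac1, a glutathione-degrading enzyme, was 5.78-fold higher (2.53 ± 0.25). The Hspa5 call ended without Kira8 replicate 1 (adjusted p = 0.0815) or 3 (0.0818).

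Growth and lipid genes moved in opposite directions. Of 28 MYC and ribosome biogenesis genes 26 fell and 2 were not called, 26 also when adjusted over the list alone (camera adjusted p = 1.93e-31; adjusted p = 0.164 with an estimated correlation). The nucleolar methyltransferase Nop2 (chromosome 6, 125131909 to 125144753, plus strand) fell from 265 ± 1.70 to 82.4 ± 11.1 CPM, the nucleolar protein Nolc1 by -2.01 ± 0.19 and spermidine synthase, Srm, by -2.25 ± 0.25. Of 25 cholesterol synthesis genes 20 rose and 5 were not called, 20 also when adjusted over the list alone (camera adjusted p = 8.11e-16; adjusted p = 0.164 with an estimated correlation). Hmgcs1 (chromosome 13, 119690379 to 119708260, plus strand) rose from 154 ± 30.4 to 501 ± 10.2 CPM and squalene synthase, Fdft1, by 1.39 ± 0.14. Autophagy and lysosome genes had 13 higher, 2 lower and 13 not called of 28, 17 and 2 when adjusted over the list alone (camera adjusted p = 3.63e-07; adjusted p = 0.178 with an estimated correlation), among them the kinase Ulk1, 6.19-fold higher (2.63 ± 0.19), and Sqstm1 (1.85 ± 0.21). Of 32 S phase genes 13 fell and 19 were not called, 14 lower when adjusted over the list alone (camera adjusted p = 4.77e-06; adjusted p = 0.364 with an estimated correlation), including the replicative helicase subunits Mcm2 (-1.15 ± 0.18) and Mcm4 (-1.0 ± 0.17).

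Effector T cell lists were mostly lower. Of 19 genes tied to pathogenic Th17 cells 7 fell, 2 rose and 10 were not called, 8 and 2 when adjusted over the list alone (camera adjusted p = 7.75e-06; adjusted p = 0.253 with an estimated correlation); Gzmb, Ccl3 and Ccl4 (-3.52 ± 0.38) are among them. The general Th17 list of 22 had 7 lower, 2 higher and 13 not called, 11 and 4 when adjusted over the list alone (camera adjusted p = 0.0292; adjusted p = 0.304 with an estimated correlation), with Il24 7.71-fold lower (-2.95 ± 0.42), while Il23r was not called (adjusted p = 0.412). T cell activation genes had 10 lower, 1 higher and 8 not called of 19, the same counts when adjusted over the list alone (camera adjusted p = 3.63e-07; adjusted p = 0.228 with an estimated correlation), for example Egr2 (-2.20 ± 0.22) and Cd40lg (-1.91 ± 0.22). Naive and quiescent T cell genes had 9 higher, 1 lower and 8 not called of 18, 10 and 1 when adjusted over the list alone (camera adjusted p = 5.07e-05; adjusted p = 0.166 with an estimated correlation), with the homing receptor Ccr7 7.35-fold higher (2.88 ± 0.22). Markers of other cells moved alongside. The B cell markers with Kira8 ranged from -0.26 for Blnk to -4.23 for Fcer2a, a difference of 3.97 ± 0.87. This pair was picked as the most extreme of 13, so whether the share of B cells differed stays open. No such comparison was made for CD8 T and NK cell markers. Of 14 CD8 T and NK cell markers, which share Gzmb with the pathogenic list, 10 fell and 4 were not called, 12 lower when adjusted over the list alone (camera adjusted p = 2.75e-14; adjusted p = 0.178 with an estimated correlation), Cd8a by -2.67 ± 0.38. Of 14 B cell markers 7 fell and 7 were not called, also 7 when adjusted over the list alone (camera adjusted p = 0.000195; adjusted p = 0.4 with an estimated correlation), Pax5 by -2.19 ± 0.33.

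The main survival genes were not called with Kira8. Bcl2 was 237 ± 61.5 CPM in None and 270 ± 37.0 with Kira8 (0.19 ± 0.24, adjusted p = 0.658), Bcl2l1, which encodes Bcl-xL, differed by 0.05 ± 0.22 (adjusted p = 0.923), and Mcl1 had an adjusted p of 0.317. The pro-apoptotic BH3-only gene Bcl2l11 (Bim) rose 2.09-fold (1.06 ± 0.21, adjusted p = 0.00379). Of 17 anti-apoptotic genes 7 rose, 2 fell and 8 were not called, 8 and 3 when adjusted over the list alone (camera adjusted p = 0.0287; adjusted p = 0.317 with an estimated correlation), among them the kinase Pim1 (1.01 ± 0.14). Of 24 STAT3 targets 7 rose, 6 fell and 11 were not called, 9 and 6 when adjusted over the list alone (camera adjusted p = 0.383; adjusted p = 0.58 with an estimated correlation), and the STAT3-induced inhibitor Socs3 changed by -0.61 ± 0.18 (adjusted p = 0.0291). The Bcl2l11 call ended without Kira8 replicate 1 (adjusted p = 0.057). The Socs3 call ended without None replicate 1 (0.055), None replicate 3 (0.0757), Kira8 replicate 1 (0.112) or Kira8 replicate 3 (0.25).

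In all, 4097 of 21239 genes differed between Kira8 and None, 2060 higher and 2037 lower, a majority that turned with library size alone (47.9% higher). That count was 1802 without Kira8 replicate 1 and 1642 without Kira8 replicate 3. In the 12 libraries edgeR called 0 of 20993 genes, with 2689 at an unadjusted p under 0.05, while DESeq2 called 1122, limma voom 3 and voom with library quality weights 4672. The 12-library count was 88 without Stattic replicate 2. All 14 genes followed in every comparison were without a call there (lowest adjusted p = 0.373).

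**Figure D2:**
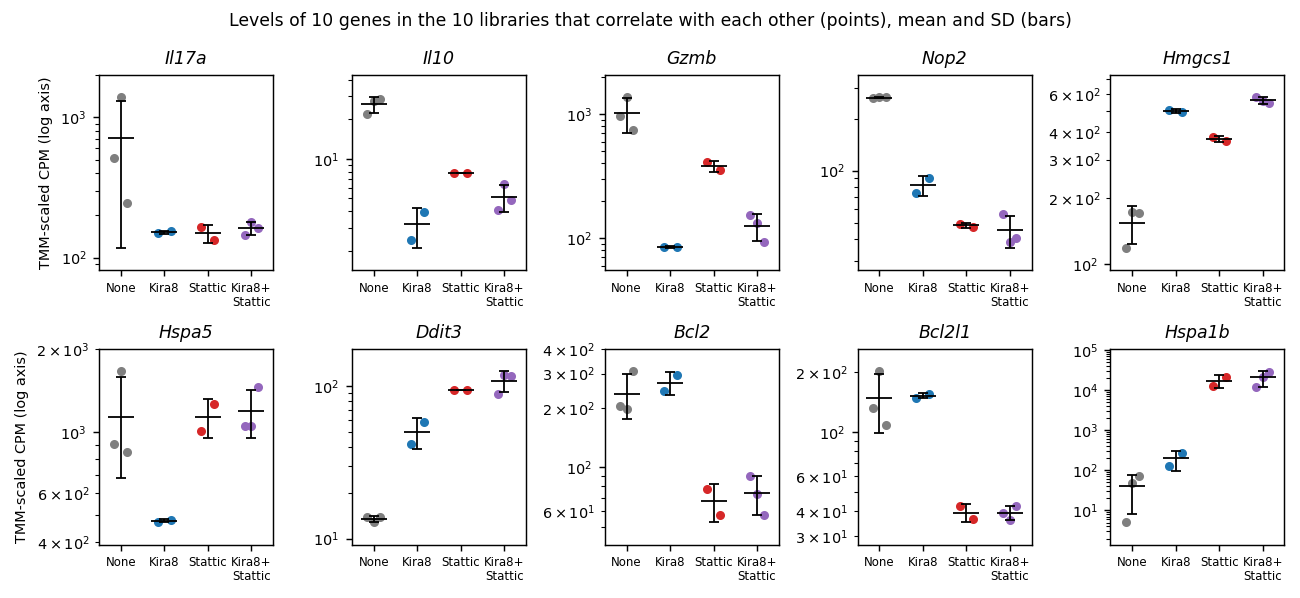
TMM-scaled CPM (log axis) of 10 named genes in the 4 groups, with a point per library of the 10 and bars for the mean and SD. Hspa1b is near 17000 and 20400 CPM with Stattic and with Kira8+Stattic against 41.6 in None, Bcl2 and Bcl2l1 are lower in the same groups, and Hspa5 is lowest with Kira8 (478 CPM).

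Stattic was compared with None to ask what a STAT3 inhibitor changes in these cells. The largest change was in inducible heat shock genes. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238, minus strand) went from 41.6 ± 33.2 to 17000 ± 5870 CPM, 408-fold (8.67 ± 0.92), and its near-identical neighbour Hspa1a (chromosome 17, 34969190 to 34972156, minus strand) rose 382-fold (8.58 ± 0.94). Reads of this pair are easily shared between the copies, and an antisense gene overlaps Hspa1a, so each value is uncertain. In the 10 libraries their sum was 2.18% to 4.93% of all counts in the 5 with Stattic. It was 0.00103% to 0.0521% in the 5 without. Stattic replicate 2 had 0.266% and Kira8 replicate 2 had 0.00054%. Hey1, a Notch-responsive repressor, rose 88.7-fold (6.47 ± 0.36), Fosb 39.3-fold (5.30 ± 0.40) and the activin antagonist Fst 35.9-fold (5.17 ± 0.40). The interferon-inducible GTPase Iigp1 (chromosome 18, 60376027 to 60392634, plus strand) fell from 378 ± 71.0 to 6.88 ± 1.63 CPM, 54.9-fold, and the cytokines Il2 (29.9-fold, -4.90 ± 0.71), Csf2 (25.1-fold, -4.65 ± 0.59) and Lta (22.5-fold, -4.49 ± 0.24) fell with it. Without None replicate 2, Il2 changed by -3.78 and Fosb by 5.93, and without None replicate 3, Hspa1b by 9.28 and Hspa1a by 9.19. Of 24 HSF1 targets and cytosolic chaperones 19 rose and 5 were not called, 19 also when adjusted over the list alone (camera adjusted p = 1.66e-13; adjusted p = 0.339 with an estimated correlation), including Dnajb4 14.2-fold (3.83 ± 0.20) and Dnajb1 11.8-fold (3.56 ± 0.24).

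Several single survival genes changed with Stattic, while neither list of apoptosis genes passed camera. Bcl2 (ENSMUSG00000057329, chromosome 1, 106538178 to 106714274, minus strand) fell from 237 ± 61.5 to 67.4 ± 14.7 CPM, 3.51-fold (-1.81 ± 0.26, adjusted p = 0.000224). Bcl2l1 (ENSMUSG00000007659, chromosome 2, 152780668 to 152831728, minus strand) fell from 148 ± 48.5 to 39.3 ± 4.08 CPM, 3.76-fold (-1.91 ± 0.24, adjusted p = 8.26e-05). Mcl1, in contrast, rose 1.77-fold (0.82 ± 0.17, adjusted p = 0.00237). Bcl2l11 rose 3.40-fold (1.77 ± 0.21) and the p53-inducible BH3-only genes Bbc3 (2.92 ± 0.34) and Pmaip1 (1.59 ± 0.18) also rose, whereas Bid fell (-2.56 ± 0.28). Counted as lists, 6 of 17 anti-apoptotic genes fell, 1 rose and 10 were not called, the same when adjusted over the list alone (camera adjusted p = 0.106; adjusted p = 0.418 with an estimated correlation). Of 22 pro-apoptotic genes 7 rose, 9 fell and 6 were not called, 7 and 10 when adjusted over the list alone (camera adjusted p = 0.562; adjusted p = 0.74 with an estimated correlation).

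Stat3 itself rose 1.52-fold with Stattic (0.60 ± 0.15, adjusted p = 0.00739), and its targets went both ways. Of 24 listed STAT3 targets 7 rose, 12 fell and 5 were not called, the same when adjusted over the list alone (camera adjusted p = 0.562; adjusted p = 0.74 with an estimated correlation). The ligand-activated factor Ahr was 6.13-fold higher (2.61 ± 0.18) and Nfkbiz was higher (1.94 ± 0.20), whereas Socs3 did not pass the test (-0.14, adjusted p = 0.54). Ern1, Xbp1 and Il23r were also not called (adjusted p = 0.0725, 0.35 and 0.445). Of 16 JAK-STAT feedback genes 5 fell, 2 rose and 9 were not called, the same when adjusted over the list alone (camera adjusted p = 0.106; adjusted p = 0.339 with an estimated correlation), with Cish at -1.31 ± 0.14 and Socs1 at -2.04 ± 0.31. Of 22 Th17 genes 10 fell, 4 rose and 8 were not called, 11 and 4 when adjusted over the list alone (camera adjusted p = 0.0447; adjusted p = 0.339 with an estimated correlation). Ccl20, the ligand of CCR6, was 12.2-fold lower (-3.61 ± 0.22), Il17a 4.80-fold (-2.26 ± 0.53, adjusted p = 0.00538), Il17f 2.69-fold (-1.43 ± 0.45, adjusted p = 0.0243), and Il10 3.31-fold (-1.73 ± 0.27). Without None replicate 2 the change was -1.35 for Il17a and -0.71 for Il17f. The Stat3 call ended without Stattic replicate 1 (adjusted p = 0.0593) and that of Il17a without Stattic replicate 3 (0.0562). That of Il17f ended without None replicate 2 (0.0711), Stattic replicate 1 (0.0803) or Stattic replicate 3 (0.146), in the fit of these groups alone (0.057) and with the replicate block (0.0765).

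Stress and metabolic lists rose with Stattic. Of 30 AP-1 and immediate early genes 19 rose, 3 fell and 8 were not called, the same when adjusted over the list alone (camera adjusted p = 2.75e-10; adjusted p = 0.299 with an estimated correlation), Klf4 by 4.58 ± 0.29 and Maff by 2.55 ± 0.17. Of 19 hypoxia response genes 14 rose, 1 fell and 4 were not called, the same when adjusted over the list alone (camera adjusted p = 3.43e-09; adjusted p = 0.214 with an estimated correlation), with the angiogenic factor Vegfa 8.20-fold higher (3.04 ± 0.24) and the mitophagy receptor Bnip3 at 2.23 ± 0.19. Ddit3 rose 7.03-fold (2.81 ± 0.18, adjusted p = 1.35e-06), and 18 of 36 ATF4 and CHOP targets rose, 5 fell and 13 were not called, 19 and 5 when adjusted over the list alone (camera adjusted p = 7.08e-06; adjusted p = 0.406 with an estimated correlation). Hspa5 was not called (0.00 ± 0.27, adjusted p = 1), although 9 of 16 ATF6 targets and ER chaperones fell, 1 rose and 6 were not called, 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00244; adjusted p = 0.418 with an estimated correlation). Glycolysis genes had 10 higher, 2 lower and 6 not called of 18, 11 and 3 when adjusted over the list alone (camera adjusted p = 0.00578; adjusted p = 0.418 with an estimated correlation), with the glucose transporter Slc2a3 at 2.38 ± 0.18. Of 45 cytosolic ribosomal protein genes 31 rose and 14 were not called, 38 higher when adjusted over the list alone (camera adjusted p = 3.79e-06; adjusted p = 0.65 with an estimated correlation), Rps24 by 1.03 ± 0.19.

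Growth and inflammatory lists fell with Stattic. Of 28 MYC and ribosome biogenesis genes 26 fell and 2 were not called, 26 also when adjusted over the list alone (camera adjusted p = 1.11e-22; adjusted p = 0.214 with an estimated correlation), Nop2 5.51-fold to 48.1 ± 1.44 CPM and the RNA polymerase I subunit Polr1b 8.77-fold (-3.13 ± 0.27). Of 22 NF-kB targets 14 fell, 3 rose and 5 were not called, 16 and 3 when adjusted over the list alone (camera adjusted p = 0.000141; adjusted p = 0.406 with an estimated correlation), Ccl4 by -3.55 ± 0.39. Of 33 interferon-stimulated genes 17 fell, 5 rose and 11 were not called, 18 and 5 when adjusted over the list alone (camera adjusted p = 0.000561; adjusted p = 0.214 with an estimated correlation), Parp14 by -2.66 ± 0.24, with Rsad2 higher (3.61 ± 0.33). Among markers of other cells, 13 of 14 B cell markers fell and 1 was not called, 13 also when adjusted over the list alone (camera adjusted p = 4.19e-06; adjusted p = 0.339 with an estimated correlation). Cd74 fell from 245 ± 63.5 to 45.3 ± 31.2 CPM, Pax5 from 35.8 ± 4.81 to 3.49 ± 1.28 CPM and Ms4a1 by -4.20 ± 0.56. Without Stattic replicate 1 the changes were -4.18 for Ccl4, -3.40 for Cd74 and -5.45 for Ms4a1, which was at -3.54 without Stattic replicate 3. CD8 T and NK cell markers had 5 lower, 2 higher and 7 not called of 14 (camera adjusted p = 0.104). Of 19 myeloid markers 4 rose and 1 fell, their median changing sign with the scaling, and of 9 stromal, 7 endothelial and 8 erythroid markers 2, 0 and 0 were called in edgeR.

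In all, 8281 of 21239 genes differed between Stattic and None, 4270 higher and 4011 lower, a majority that turned with library size alone (42.5% higher). In the 12 libraries 65 of 20993 genes were called, 22 higher and 43 lower, and all 65 were called in the same direction in the 10. They include Hey1 (6.55 ± 1.12, adjusted p = 0.0435), Iigp1 (-6.17 ± 0.65, adjusted p = 0.0109), Lta (-4.58 ± 0.42, adjusted p = 0.00532) and Lpin1 (3.47 ± 0.38, adjusted p = 0.0115). Of the MYC and ribosome biogenesis list 8 of 28 fell there, 22 when adjusted over the list alone. That count of 65 was 1199 without Kira8 replicate 2, 644 without Stattic replicate 2, 1 without None replicate 3 or Kira8 replicate 1 or 3, and 0 without None replicate 1 or 2, Stattic replicate 1 or 3 or any Kira8+Stattic replicate. In the full 12-library fit 4110 genes had an unadjusted p under 0.05, and DESeq2 called 2768, limma voom 502 and voom with library quality weights 7778. None of the 14 followed genes was called there (lowest adjusted p = 0.0572).

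**Figure D3:**
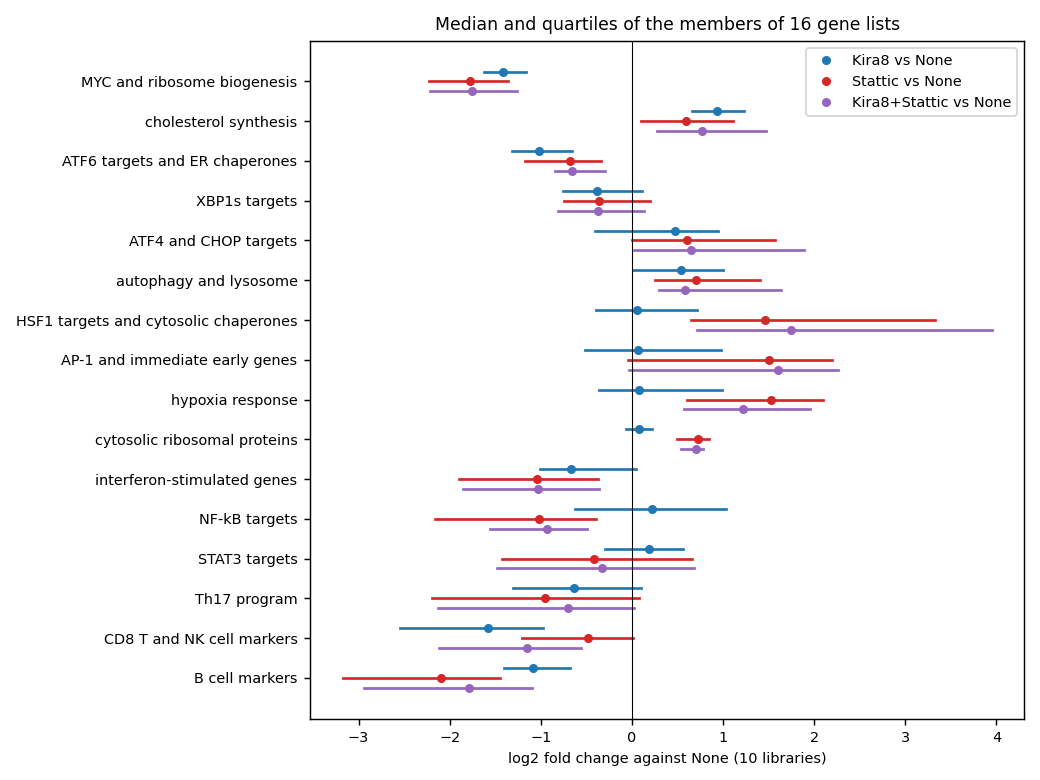
Median log2 change (points) and quartiles (bars) over the tested members of 16 gene lists, in the 10 libraries, for Kira8, Stattic and Kira8+Stattic against None. MYC and ribosome biogenesis lies below 0 in all 3 comparisons (26 of 28 members fell in each), cholesterol synthesis above 0, and HSF1 targets above 0 with Stattic and Kira8+Stattic, where 19 of 24 rose.

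Kira8+Stattic was compared with None to ask what blocking both targets changes. The result lay close to that of Stattic. Hspa1b rose 490-fold (8.94 ± 0.92) and Hspa1a 481-fold (8.91 ± 0.94), with the same limit on telling them apart, and Hey1 89.7-fold (6.49 ± 0.35), while Iigp1 (-5.65 ± 0.26), Il2 (-4.88 ± 0.59), Csf2 (-4.68 ± 0.49, 25.7-fold), Lta (-4.33 ± 0.20) and Ifng (-4.33 ± 0.46) fell. Bcl2 fell 3.21-fold (-1.68 ± 0.22) and Bcl2l1 3.77-fold (-1.91 ± 0.21), Mcl1 rose 1.77-fold (0.82 ± 0.15), Bcl2l11 3.09-fold (1.63 ± 0.19) and Ddit3 8.04-fold (3.01 ± 0.17). Il17a was 162 ± 17.9 CPM, 4.42-fold below None (adjusted p = 0.00254), Il17f 2.73-fold (adjusted p = 0.0103), Il10 5.08-fold (-2.34 ± 0.24), and Gzmb 8.15-fold (-3.03 ± 0.25). Stat3 rose 1.55-fold (0.63 ± 0.14) and Ern1 changed by 0.72 (adjusted p = 0.0333), while Xbp1, Il23r, Socs3 and Hspa5 were not called (adjusted p = 0.691, 0.948, 0.685 and 0.861). Without None replicate 2 the changes were -3.75 for Il2, -3.70 for Ifng, -1.23 for Il17a and -0.73 for Il17f, and without None replicate 3 they were 9.54 for Hspa1b and 9.52 for Hspa1a. The Ern1 call ended without Kira8+Stattic replicate 1 (0.0669), 2 (0.0811) or 3 (0.0741).

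The lists followed the same lines. HSF1 targets had 19 higher of 24 and 5 not called, 21 higher when adjusted over the list alone (camera adjusted p = 2.26e-15; adjusted p = 0.225 with an estimated correlation), Dnajb4 at 3.92 ± 0.19 and Dnajb1 at 4.05 ± 0.24. MYC and ribosome biogenesis genes had 26 lower of 28, 26 also when adjusted over the list alone (camera adjusted p = 4.63e-25; adjusted p = 0.177 with an estimated correlation), Nop2 5.86-fold lower. AP-1 genes had 18 higher, 3 lower and 9 not called of 30 (camera adjusted p = 5.42e-11; adjusted p = 0.197 with an estimated correlation), Klf4 at 4.63 ± 0.28. Cholesterol synthesis had 15 higher, 1 lower and 9 not called of 25, 16 and 1 when adjusted over the list alone (camera adjusted p = 4.98e-07; adjusted p = 0.177 with an estimated correlation), Hmgcs1 3.64-fold higher at 560 ± 18.6 CPM. Cytosolic ribosomal proteins had 36 higher of 45, 40 when adjusted over the list alone (camera adjusted p = 2.71e-06; adjusted p = 0.56 with an estimated correlation). Pathogenic Th17 genes had 11 lower, 0 higher and 8 not called of 19, 11 also when adjusted over the list alone (camera adjusted p = 2.66e-06; adjusted p = 0.225 with an estimated correlation), Tbx21, the T-bet factor of type 1 responses, at -2.63 ± 0.23 and Ccl3 at -3.37 ± 0.25. The 22 Th17 genes had 10 lower and 4 higher, also when adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.25 with an estimated correlation), Ccl20 at -3.80 ± 0.19. Of 17 anti-apoptotic genes 7 fell, 1 rose and 9 were not called, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0735; adjusted p = 0.4 with an estimated correlation). Beside these, 12 of 14 B cell markers fell, 13 when adjusted over the list alone (camera adjusted p = 9.37e-06; adjusted p = 0.301 with an estimated correlation), and 9 of 14 CD8 T and NK cell markers fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 5.18e-05; adjusted p = 0.335 with an estimated correlation).

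In all, 8676 genes differed between Kira8+Stattic and None, 4426 higher and 4250 lower (42.3% higher with library size alone). The planned fit of only these 2 groups, which holds neither outlying library, called 8282. The planned fit of all 12 libraries called 57, 28 higher and 29 lower, all 57 called in the same direction in the 10, with Iigp1 (-5.66 ± 0.64, adjusted p = 0.00984), Lta (-4.35 ± 0.42, adjusted p = 0.00704) and Lpin1 (3.85, adjusted p = 0.00704) among them. The count of 57 became 694 without Kira8 replicate 2, 1053 without Stattic replicate 2, 6 without Kira8 replicate 1 or Stattic replicate 3, 2 without Kira8 replicate 3, and 0 without any None or Kira8+Stattic replicate or Stattic replicate 1. Of the 14 followed genes none was called in the 12 libraries (lowest adjusted p = 0.0551).

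Kira8+Stattic was compared with Kira8 to ask what Stattic added to Kira8. Heat shock genes rose and several survival genes fell. Hspa1a was higher by 6.74 ± 1.03 and Hspa1b by 6.66 ± 1.00 (7.32 without Kira8 replicate 3) and Dnajb4 by 3.15 ± 0.22, while Iigp1 was 31.1-fold lower (-4.96 ± 0.26), the chemokine Cxcl10 changed by -4.53 ± 0.37 and Cyp1a1, a target of AHR, by -5.90 ± 0.71. Bcl2 was 3.66-fold lower (-1.87 ± 0.24, adjusted p = 0.000204), Bcl2l1 3.89-fold (-1.96 ± 0.22), the inhibitor of apoptosis Birc3 4.95-fold (-2.31 ± 0.21), Bcl2l2 3.42-fold (-1.77 ± 0.17) and Pim1 changed by -1.59 ± 0.14. Of 17 anti-apoptotic genes 9 fell, 3 rose and 5 were not called, 10 and 4 when adjusted over the list alone (camera adjusted p = 0.000125; adjusted p = 0.347 with an estimated correlation). Hspa5 was 2.49-fold higher (1.31 ± 0.29, adjusted p = 0.00478) and Ddit3 rose further (1.11 ± 0.19, adjusted p = 0.000915), whereas Il17a (0.10, adjusted p = 0.905), Il17f (0.51, adjusted p = 0.402) and Il10 (0.68, adjusted p = 0.0694) were not called, nor were Ern1, Stat3, Il23r and Bcl2l11 (0.797, 0.504, 0.317 and 0.0616). Xbp1 (0.63, adjusted p = 0.0189), Socs3 (0.70, 0.0104) and Mcl1 (0.56, 0.0303) were higher. These calls ended without Kira8 replicate 3 (0.24, 0.123 and 0.202), for Xbp1 also without Kira8+Stattic replicate 3 (0.0644), for Socs3 and Mcl1 without Kira8 replicate 1 (0.0528 and 0.143), and for Mcl1 without Kira8+Stattic replicate 2 (0.0852) or 3 (0.105), with library size alone (0.0539) or without the filter (0.0555).

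By list, HSF1 targets had 20 higher of 24, 22 when adjusted over the list alone (camera adjusted p = 3.88e-16; adjusted p = 0.347 with an estimated correlation), and AP-1 genes 21 higher, 1 lower and 8 not called of 30, 21 and 2 when adjusted over the list alone (camera adjusted p = 1.58e-12; adjusted p = 0.347 with an estimated correlation), among them Klf10 (1.95 ± 0.17). NF-kB targets had 14 lower, 2 higher and 6 not called of 22, 15 and 2 when adjusted over the list alone (camera adjusted p = 2.5e-08; adjusted p = 0.367 with an estimated correlation), Nfkbie by -2.01 ± 0.18. Of 18 glycolysis genes 12 rose, 1 fell and 5 were not called, 13 and 1 when adjusted over the list alone (camera adjusted p = 1.53e-06; adjusted p = 0.347 with an estimated correlation), Tpi1 by 2.07 ± 0.20 and Ldha by 1.39 ± 0.18. B cell markers had 4 lower and 10 not called of 14, 6 lower when adjusted over the list alone (camera adjusted p = 0.0637; adjusted p = 0.684 with an estimated correlation), and CD8 T and NK cell markers 3 higher and 11 not called (camera adjusted p = 0.0776; adjusted p = 0.684 with an estimated correlation). In all, 6514 genes differed, 3116 higher and 3398 lower. Without Kira8 replicate 1 there were 3579 and without Kira8 replicate 3 there were 3270. All 12 libraries together gave 0 in edgeR, with 2536 at an unadjusted p under 0.05, DESeq2 1226, limma voom 1 and voom with library quality weights 9279. That 0 became 27 without Kira8 replicate 2 and 342 without Stattic replicate 2.

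Kira8+Stattic was compared with Stattic to ask what Kira8 added to Stattic, and few genes differed. Gzma, a granzyme of cytotoxic lymphocytes (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981, minus strand), was 52.1 ± 13.5 CPM with Stattic and 11.1 ± 1.89 with both inhibitors, 4.70-fold lower (-2.23 ± 0.21, adjusted p = 0.00379). Gzmb (-1.60 ± 0.25, adjusted p = 0.0981) and Prf1 (-1.23 ± 0.31, adjusted p = 0.883) did not pass the test. Of 14 CD8 T and NK cell markers 1 fell and 13 were not called, 4 lower when adjusted over the list alone (camera adjusted p = 1.5e-16; adjusted p = 0.238 with an estimated correlation). Of 19 pathogenic Th17 genes 0 were called, 5 lower when adjusted over the list alone (camera adjusted p = 5.8e-10; adjusted p = 0.252 with an estimated correlation). Of 4 metallothioneins and zinc response genes 0 were called, 2 higher when adjusted over the list alone (camera adjusted p = 6.83e-06; adjusted p = 0.189 with an estimated correlation), the zinc exporter Slc30a1 at 1.15 ± 0.17 (adjusted p = 0.0981). Of 28 XBP1 targets, 16 ER chaperones and 14 B cell markers 0 were called (camera adjusted p = 0.289, 0.14 and 0.0801), and all 14 followed genes had an adjusted p of 1.

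In all, 3 of 21239 genes differed, 2 higher and 1 lower, with 874 at an unadjusted p under 0.05. The higher ones fall outside the rule for named genes and were chosen after their values were seen. Gm44503 (4.31 ± 0.484 CPM with both inhibitors, no count in the None, Kira8 and Stattic libraries of the 10; adjusted p = 0.0193) overlaps Dyx1c1 and Ccpg1 on the same strand, and Gm21982 (22.0 ± 12.9 against 0.775 ± 0.212 CPM, adjusted p = 0.00529) overlaps Rbm42 and Haus5, so their counts are uncertain. With limma voom both calls ended (0.0983 and 0.316). The count of 3 was 15 without None replicate 1, 5 without None replicate 2 and 1 without Stattic replicate 3, while DESeq2 called 51. With all 12 libraries edgeR called 0, with 1050 at an unadjusted p under 0.05, DESeq2 18, and limma voom 0 with and without library quality weights.

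The interaction asks whether the Kira8 change differed with and without Stattic. It did for 1810 genes, against at most 1 in 20 simulations in which the Kira8 change was the same with and without Stattic. These assume independent libraries. Of 100 divisions of the same libraries, the real one included, 5 called as many genes, up to 6966. The divisions shuffle the labels of all groups, so the Stattic change can enter the shuffled contrast. They therefore cannot decide on chance, which stays open. Ifng (3.5 ± 0.69), Ccl4 (3.38 ± 0.50), the tensin gene Tns4 (3.54 ± 0.75), Prag1 (3.14 ± 0.31) and the chemokine Xcl1 (3.04 ± 0.40) had positive values, having fallen with Kira8 alone. The receptor accessory gene Ramp3 (-3.98 ± 0.60), the prostaglandin synthase Hpgds (-3.78 ± 0.43) and Vps37b (-3.46 ± 0.29) had negative values, having risen. Clstn3 (-3.29 ± 0.70) and the phosphodiesterase Pde2a (-4.75 ± 1.31) also had negative values, having risen. Ifng was at 169 CPM in None, 9.52 with Kira8, 13.1 with Stattic and 8.37 with both. Vps37b was at 22.8, 249, 259 and 257 CPM. Stattic alone had thus moved these 2 genes about as far as Kira8 alone. Apart from Prag1, it had also moved the other genes just named the same way. Ccl4 was at 146, 12.7, 12.5 and 11.3 CPM, and Hpgds, moved less far, at 0.787, 11.2, 5.43 and 5.64. Their interactions do not show that Stattic cancelled the Kira8 change. Prag1 went otherwise, at 23.9, 2.49, 16.5 and 15.2 CPM. Il10 (26.0, 3.18, 7.85 and 5.11 CPM) and Ddit3 (13.5, 50.3, 94.8 and 108) had moved the same way with each inhibitor alone. Il10 (2.41 ± 0.38, adjusted p = 0.00419), Ddit3 (-1.70 ± 0.25, adjusted p = 0.00318) and Bcl2l11 (-1.20 ± 0.29, adjusted p = 0.0265) were called, but Il17a (2.36, adjusted p = 0.0636), Hspa5 (1.31, adjusted p = 0.0611), Xbp1 (0.85, adjusted p = 0.0569), Bcl2 (adjusted p = 0.96) and Bcl2l1 (0.965) were not, nor were the other 6 followed genes (adjusted p from 0.055 for Socs3 to 0.933 for Il23r). Values moved without Stattic replicate 1 for Tns4 (4.62), Ifng (4.19), Ccl4 (4.01) and Pde2a (-5.68), without Stattic replicate 3 for Tns4 (2.93) and Pde2a (-1.13), and without None replicate 2 for Ifng (2.86) and Il17a (1.44, adjusted p = 0.0452). Calls ended for Tns4 and Ifng without Kira8 replicate 1 (0.0592 and 0.0535), Kira8 replicate 3 (0.0768 and 0.0555) or Stattic replicate 3 (0.0534 and 0.0531), for Bcl2l11 without the same libraries (0.133, 0.0627 and 0.126), for Clstn3 without Kira8 replicate 1 (0.0651), and for Pde2a without any single library other than Stattic replicate 1 (0.0594 to 0.565) and in limma voom (0.3).

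By list, 22 of 28 MYC and ribosome biogenesis genes had positive interactions and 6 were not called, 26 positive when adjusted over the list alone (camera adjusted p = 3.61e-28; adjusted p = 0.162 with an estimated correlation), Nolc1 at 2.25 ± 0.26. Of 16 ATF6 targets and ER chaperones 8 were positive, 12 when adjusted over the list alone (camera adjusted p = 3.64e-09; adjusted p = 0.32 with an estimated correlation), Sdf2l1 at 2.32 ± 0.24. Of 25 cholesterol synthesis genes 7 were negative, 12 when adjusted over the list alone (camera adjusted p = 6.63e-08; adjusted p = 0.243 with an estimated correlation), Fdft1 at -1.20 ± 0.19. Of 28 autophagy genes 9 were negative and 1 positive, 14 and 1 when adjusted over the list alone (camera adjusted p = 5.22e-07; adjusted p = 0.243 with an estimated correlation), Ulk1 at -2.74 ± 0.27. Stattic alone had moved these examples the same way as Kira8 alone. In None, Kira8, Stattic and both, Nolc1 was at 376, 93.6, 91.4 and 108 CPM and Ulk1 at 38.5, 238, 174 and 161 CPM. Such interactions do not show that Stattic cancelled the Kira8 change. Markers of other cells followed, with 5 of 14 CD8 T and NK markers and 4 of 14 B cell markers positive, 7 of each when adjusted over the list alone (camera adjusted p = 1.4e-05 and 2.73e-05; adjusted p = 0.491 for each with an estimated correlation). In all, 1810 genes had an interaction, 966 positive and 844 negative. The count was 498 without Kira8 replicate 1, 515 without Kira8 replicate 3, 680 without Stattic replicate 3, 1144 without Kira8+Stattic replicate 2 and 1137 without replicate 3 of that group. The 12-library fit called 0 in edgeR, with 3542 at an unadjusted p under 0.05, DESeq2 611, limma voom 0 and voom with library quality weights 1545.

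**Figure D4:**
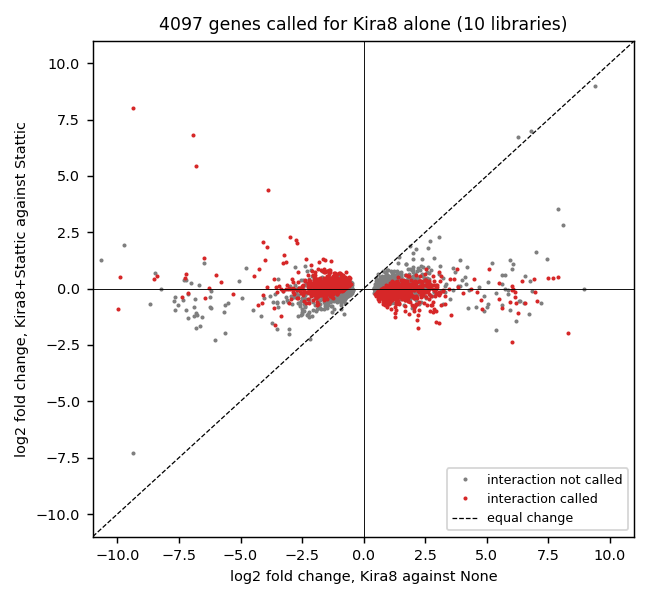
Log2 change with Kira8 against None (x axis) and with Kira8+Stattic against Stattic (y axis) for the 4097 genes called for Kira8 alone in the 10 libraries. Red points are genes with a called interaction and the dashed line marks equal change; the points lie along the horizontal axis, the slope being 0.02.

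Over the 4097 genes called for Kira8 alone, the median absolute log2 change was 1.04 without Stattic and 0.15 with it, and 49.2% kept their sign. The interaction was called opposite to the Kira8 change for 1729 of them, 42.2%, and in its direction for 0 in edgeR. The Kira8 and None libraries enter the interaction with the opposite sign, which favours that direction, but the simulations with equal Kira8 changes gave at most 1 such gene. Of the 2391 genes called in the same direction for each inhibitor alone, 1268 had an interaction against that direction and 0 along it, where these simulations gave at most 1 and 0. Across the 9730 genes called for either inhibitor alone, the change with both had a slope of 0.58 on the sum of the single changes (0.241 to 0.295 in simulations of unchanged groups, 0.845 to 0.863 in those with equal Kira8 changes), with a median absolute change of 1.06 against 1.69 for the sum. The changes with both correlated at 0.944 across genes with those of Stattic and at 0.523 with those of Kira8, where unchanged groups gave 0.384 to 0.464 and 0.388 to 0.469 through the shared None libraries, and equal Kira8 changes gave 0.914 to 0.919 and 0.673 to 0.687. For these slopes and correlations the simulations kept the genes called in the real data. Those with equal Kira8 changes took the observed single changes as true. Choosing genes by the same single changes can lower the observed slope, and the simulated ranges leave this out. The gap between 0.58 and 0.845 to 0.863 may thus come in part from that choice. In the 12 libraries the slope was 0.63 on 65 genes, and 0.38 on 3314 genes with DESeq2.

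Kira8 and Stattic changed many genes alike. Of all genes, 1122 were higher and 1269 lower with each inhibitor, against 414 and 385 for independent lists, and 257 went opposite ways. The fold changes of all genes correlated at 0.458, against 0.372 on average in 20 simulations of unchanged groups set against shared controls (0.329 to 0.41). These gave no shared calls, but no gene was changed in them. That does not show how many shared calls common controls add to real changes. The covariance of the fold changes was 1.675 against 0.266 in the simulations, a difference of 1.41. The None libraries were not split between the 2 inhibitors here, so part of the excess may come from the shared controls. The overlap of 2391 was 1183 without Kira8 replicate 1 and 1117 without Kira8 replicate 3. In the 12 libraries no gene was called for both, and without Stattic replicate 2 there were 53. The covariance in the 12 was 5.049 against 0.807, but each inhibitor there includes 1 outlying library. These outlying libraries correlated at 0.668 with each other, so the value in the 12 does not add to a shared effect.

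Stattic was compared with Kira8 directly. Heat shock genes were higher with Stattic, Hspa1a by 6.41 ± 1.03 and Hspa1b by 6.40 ± 1.01 (7.05 without Kira8 replicate 3), together with Ankrd55 (5.96 ± 0.85; 5.35 and 6.96 without Kira8 replicates 1 and 3, 6.56 and 4.86 without Stattic replicates 1 and 3). Cxcl10 (-5.26 ± 0.46), Iigp1 (-5.09 ± 0.31) and Lad1 (-4.90 ± 0.65) were lower. Bcl2 was 4.00-fold lower with Stattic than with Kira8 (-2.0 ± 0.28, adjusted p = 0.000383) and Bcl2l1 3.89-fold (-1.96 ± 0.25, adjusted p = 0.000248), while Il10 was higher (1.30 ± 0.29, adjusted p = 0.00564) and Il17a did not differ beyond the spread (-0.02, adjusted p = 0.993). Ddit3 (0.92, adjusted p = 0.00495), Hspa5 (1.25, 0.00963), Mcl1 (0.56, 0.0436) and Bcl2l11 (0.70, 0.0371) were higher. Without Kira8 replicate 1 the calls of Il10 (0.0718), Ddit3 (0.0762), Hspa5 (0.0671), Mcl1 (0.166) and Bcl2l11 (0.0772) ended. Those of Hspa5, Mcl1 and Bcl2l11 also ended without Kira8 replicate 3 (0.0657, 0.229 and 0.252) or Stattic replicate 3 (0.0636, 0.17 and 0.252), and that of Mcl1 without Stattic replicate 1 (0.103) or Kira8+Stattic replicate 2 (0.0649). In all, 6106 genes differed, 2906 higher and 3200 lower with Stattic. The count was 3471 without Kira8 replicate 1, 3180 without Kira8 replicate 3 and 4040 without Stattic replicate 3. With all 12 libraries edgeR called 0, with 2491 at an unadjusted p under 0.05, DESeq2 1604, limma voom 0 and voom with library quality weights 6810; without Kira8 replicate 2 there were 72 and without Stattic replicate 2 there were 159.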

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

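The interaction in the 10 libraries was tested after the data were examined; the 2 tests of explanations for it were chosen before their results were seen, and the simulations set beside them afterwards.

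For 1810 genes the Kira8 change with Stattic differed from that without it by the test of the difference itself. Of 100 divisions of the same libraries, the real one included, 5 called as many, up to 6966. Since the divisions shuffle the labels of all groups, the Stattic change can enter them, so they cannot decide on chance. Values are given as the Kira8 change with Stattic minus that without, on the log2 scale. By the naming rule, the largest positive ones were Tns4 at 3.54, Ifng at 3.5, Ccl4 at 3.38, Prag1 at 3.14 and Xcl1 at 3.04. On the negative side they were Pde2a at -4.75, Ramp3 at -3.98, Hpgds at -3.78, Vps37b at -3.46 and Clstn3 at -3.29. Stattic alone had moved Ifng (13.1 CPM) and Vps37b (259 CPM) about as far as Kira8 alone (9.52 and 249 CPM). It had moved the others of these genes the same way as Kira8 alone, except that Prag1 moved little (16.5 against 2.49 CPM). The calls of Tns4, Ifng, Pde2a and Clstn3 ended without single libraries. For Pde2a the adjusted p without 1 library reached 0.565 (without Stattic replicate 3).

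The pattern behind these values is that few genes differed when Kira8 was added to Stattic. Lower power of that comparison as the whole cause is argued against: over genes that moved over 2-fold in a single Kira8 and None pair, the slope of the change with Stattic on that without was -0.121 to 0.173, against 0.603 to 0.863 between independent repeats of the Kira8 change, a ratio of at most 0.29. A deviation of the None libraries stays open: 34.0% of Kira8-called genes (1394) returned toward None in Kira8+Stattic compared with Kira8, but the effect of Stattic itself moves genes that way (9.73% to 10.9% in 20 simulations with equal Kira8 changes), as would a deviation shared by both Kira8 libraries. Both values rest on 2 libraries each of Kira8 and Stattic. Also open, and untested, is a biological difference, for example that the response to Stattic may override or block that to Kira8, and whether Kira8 reached its target in the presence of Stattic, which gene counts do not show.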

How the results depend on the processing

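The fits of 10 libraries, those with library quality weights and every result on the 10 libraries were chosen after the data were examined; the other alternatives were fixed beforehand. Unless a cause is named, the cause was not tested. Counts are given in the order Kira8, Stattic and Kira8+Stattic against None, Kira8+Stattic against Kira8 and against Stattic, interaction, and Stattic against Kira8.

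With all 12 libraries edgeR called 0, 65, 57, 0, 0, 0 and 0 genes. DESeq2 called 1122, 2768, 1955, 1226, 18, 611 and 1604. Voom with library quality weights, which gave Kira8 replicate 2 a weight of 0.076 and Stattic replicate 2 of 0.05, called 4672, 7778, 9959, 9279, 0, 1545 and 6810. The 10 libraries gave 4097, 8281, 8676, 6514, 3, 1810 and 6106. Limma voom called 3, 502, 954 and 1 in the first 4, RLE size factors 3, 174, 194 and 2 there and 1 in the last, and a filter of more than 1 CPM in 3 libraries 3, 295, 281 and 2 there and 1 in the last. For Stattic and for both inhibitors against None, library size alone gave 0 and 0, no filter 5 and 6, the 1.5-fold test 18 and 6, and a fit of only the groups compared 0 and 8282. The fit behind 8282 holds neither outlying library. No fit of fewer groups exists for the interaction. Leaving out a library gave 0 to 88, 0 to 1199, 0 to 1053, 0 to 342, 0 to 0, 0 to 0 and 0 to 159.

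In the 10 libraries the 1.5-fold test called 1359, 4865, 5018 and 2912 in the first 4, 461 for the interaction and 2872 for Stattic against Kira8, being a stricter test by construction. For Kira8+Stattic against Stattic, DESeq2 called 51, limma voom 1, no filter 5 and only these groups 23, against 3; DESeq2 called 3119 for the interaction. Leaving out a library gave 1642 to 4118, 5534 to 8649, 6937 to 9091, 3270 to 7457, 1 to 15, 498 to 2066 and 3180 to 7073. Where this leaves a lone Kira8 or Stattic library, that library is assumed to vary like those of the other groups.

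Replicate numbers are shared by the groups, and the fit with a replicate block was compared. In the 12 libraries the block gave 8 genes for Stattic and 6 for both inhibitors against None, and 0 elsewhere. In the 10 it gave 4423, 8062, 8947, 6660, 4, 1784 and 6519, an overlap of 2585 and a slope of 0.54. Deviations from the group means of libraries with the same number correlated at -0.173 to 0.563 in the 12 (7 of 18 over 0.1). The 0.563 is that of the outlying libraries, Kira8 replicate 2 and Stattic replicate 2. Libraries with different numbers there correlated at -0.564 to 0.527 (7 of 36 over 0.1), so the 12 show no separate effect of the number. In the 10, libraries with the same number correlated at 0.017 to 0.218 (2 of 13 over 0.1), and those with different numbers at -0.151 to 0.074. All same-number values in the 10 lay above 0, but they are not independent. In a group of 2 libraries the deviations mirror each other. Kira8 and Stattic thus gave 0.084 for each same-number pair and -0.084 for each other pair. A shared effect of the replicate number is not excluded. The planned fit has no block, and the counts with the block are those given here.

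Camera called 23, 24, 25, 17, 12 and 26 lists in the first 6 comparisons with 12 libraries, and 27, 22, 25, 17, 11 and 17 with 10. With an estimated correlation 0 lists were called in each. Fry called 0, 4, 3, 0, 0 and 0 with 12 libraries, and 22, 28, 30, 20, 0 and 7 with 10. Without the filter 26 were called for Kira8+Stattic against Stattic in the 12. Leaving out a library gave 23 to 33, 20 to 27, 24 to 27, 14 to 23, 5 to 28 and 16 to 36 with 12, the 5 and 28 being without Stattic replicate 2 and without Stattic replicate 1, and the 16 without Kira8 replicate 2. With 10 it gave 22 to 28, 19 to 24, 24 to 27, 16 to 18, 10 to 16 and 14 to 20.

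The overlap of Kira8 and Stattic was 0 genes in the 12 libraries, 568 with DESeq2, 3 with RLE size factors, 2391 in the 10 libraries, and 0 to 53 and 1117 to 2429 without single libraries. The slope of the change with both on the sum was 0.63 in the 12, 0.38 with DESeq2 and 0.56 to 0.66 without single libraries (2 fits with a value). In the 10 it was 0.58, with 0.45 in DESeq2, 0.55 without the filter, and 0.53 to 0.60 without single libraries.

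Some genes changed sign from the 12 libraries, where none of them was called, to a setting that called them. Changes of sign without a call in either fit are not listed. Given with quality weights, in the 10 libraries and in the 10 with the replicate block, these are Sdf2l1 with Kira8 (0.61 in the 12; -1.89, -1.91 and -1.93) and in the interaction (-2.10; 2.27, 2.32 and 2.36), Gpr83 with Kira8 (0.54; -3.02, -2.99 and -3.26), Isg20 with Kira8 (1.43; -1.64, -1.95 and -1.77) and Ebf1 with Stattic (1.27; -1.14, -1.13 and -1.0). Gm21982 in Kira8+Stattic against Stattic went from -0.53 to 4.82 and 4.73 in the fits of 10 libraries. Over all genes reported and settings, 13149 values stayed called or stayed without a call, 1258 gained a call, 560 lost it and 17 reversed. A reversal was counted only where at least 1 of the 2 fits called the gene. The 13149 therefore include values without a call in either fit, whose sign was not compared.

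With library size alone the median log2 change moved by over 0.1 in the 10 libraries for Stattic (-0.156) and both inhibitors (-0.154) against None, both against Kira8 (-0.123) and Stattic against Kira8 (-0.102). In the 12 it moved by up to 0.322 (interaction). The share of higher calls moved by under 10 percentage points, but its majority turned with library size alone in the 10 libraries for Kira8 (50.3% to 47.9%), Stattic (51.6% to 42.5%) and both (51.0% to 42.3%) against None; for both against Kira8 it went from 47.8% to 38.2% and for Stattic against Kira8 from 47.6% to 37.8%. Library size alone called 0 genes in the 12, so no split is given there. With RLE size factors the majority turned for Kira8 against None in the 10 libraries (50.3% to 49.5%). It also turned for both inhibitors against None in the 12 (49.1% to 51%). Depth limits Stattic replicate 2 most, where a count of 3 is 0.323 CPM.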

Other observations

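The fit of 10 libraries, the tests for DNA and for a wrong label, the comparison of B cell markers and all label splits were chosen after the data were examined; the tests on X-linked genes and on depth were fixed before their results were seen.

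Other lists were tested for Stattic and for both inhibitors against None in the 10 libraries (n = 2 for Stattic, n = 3 for None and Kira8+Stattic). Replication-dependent histone genes had 8 higher and 8 not called of 16 with Stattic, and 11 higher and 5 not called with both inhibitors (camera adjusted p = 0.0173 and 0.00747; adjusted p = 0.339 and 0.25 with an estimated correlation). The linker histone gene Hist1h1c rose by 2.71 ± 0.30 with Stattic and 2.58 ± 0.28 with both. The list of 27 NRF2 targets, genes of oxidant defence, did not pass with Stattic, with 10 higher, 4 lower and 13 not called (camera adjusted p = 0.149; adjusted p = 0.659 with an estimated correlation), although the heme oxygenase Hmox1 rose by 4.32 ± 0.39, 19.9-fold, and glutathione reductase, Gsr, fell (-1.22 ± 0.19). With Stattic, regulatory T cell genes had 9 lower, 1 higher and 5 not called of 15 (camera adjusted p = 0.00547; adjusted p = 0.259 with an estimated correlation): Il2ra, the IL-2 receptor alpha chain, was 5.72-fold lower (-2.52 ± 0.20), Foxp3 3.47-fold (-1.79 ± 0.28) and Ikzf4 6.64-fold (-2.73 ± 0.30), with Ctla4 higher (1.19 ± 0.16). Naive and quiescent T cell genes had 8 higher, 2 lower and 8 not called of 18 with Stattic (camera adjusted p = 0.000232; adjusted p = 0.214 with an estimated correlation), the antiproliferative gene Tob1 20.7-fold (4.37 ± 0.16).

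Further lists differed between Kira8 and None. Of 10 inhibitory receptors 8 fell, 1 rose and 1 was not called (camera adjusted p = 8.26e-05; adjusted p = 0.25 with an estimated correlation), Pdcd1, which encodes PD-1, by -1.83 ± 0.19, with Ctla4 higher (1.00 ± 0.16). Pdcd1 was higher again with both inhibitors than with Kira8 (1.39 ± 0.19), and its interaction was 1.56 ± 0.26 (adjusted p = 0.00537 in edgeR). Of 25 p53 targets 7 rose, 2 fell and 16 were not called (camera adjusted p = 0.00103; adjusted p = 0.166 with an estimated correlation), Trp53inp1 by 2.81 ± 0.18, 7.01-fold, and Pmaip1 by 1.46 ± 0.18. Trp53inp1, Pmaip1 and Ctla4 also rose with Stattic (2.44, 1.59 and 1.19). The zinc exporter Slc30a1 rose with Kira8 (1.38 ± 0.17), as did the metallothionein Mt1 (1.21 ± 0.23). In Kira8+Stattic against Kira8, nuclear-encoded respiratory chain genes had 18 higher, 2 lower and 21 not called of 41 (camera adjusted p = 0.000929; adjusted p = 0.684 with an estimated correlation), for example Ndufb10 (0.94 ± 0.18).

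Kira8 replicate 2 and Stattic replicate 2 stand apart from the other 10 libraries. Low depth alone is argued against, since the other libraries thinned to 9275672 counts still correlated at 0.855 or more with each other and had counts for only 2.3% to 4.4% of olfactory receptor genes. A wrong label is argued against for Kira8 replicate 2, which correlated best with its own group over 2230 genes above 100 CPM, by a lead of 0.087 (0.06 to 0.11 over resampled genes, which are not independent), and among the 10 over all 14372 genes (0.452 with Kira8 replicate 3). For Stattic replicate 2 it stays open between Stattic and Kira8+Stattic: the lead was 0.017 (0.004 to 0.027), but over all 14372 genes it correlated at 0.391 with each other Stattic library, 0.394 with Kira8+Stattic replicate 1 and 0.668 with Kira8 replicate 2. Reads from genomic DNA are a candidate explanation: olfactory receptor genes had counts for at least 32.7% in both, and Y-linked genes for 52.0% and 43.1% of 1562 against 1.2% to 3.3%, but the ratio of X-linked to autosomal counts per kilobase of silent genes was 0.31 (0.19 to 0.43) in Kira8 replicate 2 and 0.23 (0.12 to 0.36) in Stattic replicate 2, below the 0.5 of male DNA, so this stays open and no biological explanation was tested.

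B cell marker genes were lower in Stattic-treated libraries, with all 13 markers that reached 5 CPM in None called lower (median -2.12), 12 of them with both inhibitors (-2.09) and 7 with Kira8 (-1.09). These Th17 cultures come from lymph nodes, and a lower share of contaminating B cells would lower every marker by a common factor. Whether that is the whole cause stays open: the markers with Stattic ranged from -1.13 for Ebf1 to -5.27 for Fcer2a (-6.24 without Stattic replicate 1), a difference of 4.13 ± 0.84 or 4.93 standard errors, but this pair was picked as the most extreme of 13, Ebf1 changed by 1.27 in the 12 libraries, and no allowance was made for the choice. Cd74 and Ighm, the most abundant of them, were at 245 ± 63.5 and 187 ± 35.9 CPM in None and 45.3 ± 31.2 and 77.2 ± 34.2 with Stattic. A change of expression within B cells, alone or beside a lower share, may be involved and was not tested, and the Ebf1 and Ighm calls ended without Stattic replicate 3 (adjusted p = 0.0671 and 0.0572). No sort or gate is named in the labels.

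Other divisions of the same libraries were tested for each count. Counts of divisions include the real one. With 3 against 3 libraries there are 10 divisions, so the share as large as the real one cannot go under 0.1. In the 12 libraries, edgeR called 65 genes for Stattic and 57 for both inhibitors against None, and at most 0 in any other division (1 of 10 as large in each case). The 0 calls for Kira8 against None, for both inhibitors against Kira8 or Stattic, and for Stattic against Kira8 were matched by all 10 divisions, as any count of 0 must be, so this says nothing on chance. Lists called were 23 for Kira8 (highest other 29, 5 of 10 as large), 24 for Stattic (25, 2 of 10), 25 for both against None (19, 1 of 10), 17 against Kira8 (24, 8 of 10) and 12 against Stattic (25, 7 of 10). For the interaction the 0 genes are likewise matched by 100 of 100 divisions whatever the data (highest other 0). Of these divisions 9 gave at least the 26 lists (highest 32). In the 10 libraries both inhibitors against None gave 8676 genes and 25 lists, the highest other division 0 and 22 (1 of 10 as large in each case). The interaction gave 1810 genes, and 5 of 100 divisions as many, up to 6966, while 31 gave at least the 17 lists, up to 29. The interaction divisions, here and in the 12, shuffle the labels of all groups, so the changes against None can enter the shuffled contrast. They cannot decide on chance, which stays open for genes and lists. Why a division called 6966 genes was not tested.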
